A study of Mus musculus with 12 samples.

How the data were processed

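RNA was measured on 12 mouse MG_U74Av2 oligonucleotide arrays, 3 for each of 4 groups of fibroblasts of the 2C5/7 line, which carry no functional MyoD or Myf5 gene. Each group had been infected with a retrovirus coding for MyoD, for Myf5, for myogenin, or for the green fluorescent protein hrGFP alone. Per the labels, the factor and hrGFP were made from the same viral transcript, the cells were sorted for fluorescence to a purity of 75 to 85% without cloning, and adherent cells were grown in medium with 10% fetal calf serum. Total RNA was taken from them. The labels name myogenin and hrGFP as controls. Arrays were grouped by their titles, which also carry a replicate number. Nothing in the labels says that replicates are separate cultures, so the p-values measure the spread between samples, part of which may be technical.

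The deposited values are intensity signals, one per probe set and array, made with MAS5 per the submitters' processing notes. The version of MAS5, its scaling and its detection calls are not given in the sources used here. The table held 12488 probe sets, of which 66 were array controls, and no column was identical to another. The trimmed mean signal, leaving out 2% at each end, ran from 41.4 to 103 over the arrays, a ratio of 2.50, so the signals had not been brought to a common target. The design allowed a difference of 10% and asked for quantile normalization beyond it, which was used. The columns of myogenin replicates 2 and 3 were rounded to 1 decimal. The experiment information files deposited with the arrays hold other information, the chip lot and the day of each hybridization, and were used only to find array batches; the image and probe-level files were not used here.

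A pseudocount of 6.3, the 25th percentile of the signals, was added before log2 transformation and quantile normalization in limma 3.58.1 under R 4.3.3 with statmod 1.5.0. It understates the change of probe sets with low signal. Probe sets with a signal above 15.0, the 40th percentile, in at least 3 of the 12 arrays were kept, which left 8485 probe sets for 6277 genes out of 12422 without the array controls. One linear model with a mean per group was fitted to all 12 arrays, with 8 residual degrees of freedom. Moderated statistics with a trend in the variance gave p-values, adjusted by the Benjamini-Hochberg method over the probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. Each of the 6 pairs of groups was compared. The comparison of MyoD with Myf5 is also the test of the difference between their changes against hrGFP. For arrays, their number limits the precision.

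Probe sets were matched to genes with the table of the array supplied for this work: 10833 had 1 gene symbol, 396 had several and 1193 were not listed. Of the first, 10817 were found by gene number in a RefSeq table of the GRCm38.p6 assembly, 0 of them under another symbol. Only probe sets with 1 symbol are named as genes. The build behind the array is not given in the sources used here, so no coordinates are printed.

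The 24 gene lists, the filter, the model, the tests and most alternatives were chosen before the data were examined. The lists cover myogenic transcription factors, sarcomere and contraction, muscle calcium handling, neuromuscular junction, muscle energy metabolism, myoblast adhesion and the dystrophin complex, cell cycle and DNA replication, cell cycle exit and D cyclins, inhibitors of myogenesis, fibroblast and extracellular matrix, the insulin-like growth factor system, TGF-beta and BMP signalling, interferon response, smooth muscle, cardiac, adipocyte, cartilage and bone, macrophage and leukocyte, endothelial, epithelial and neural markers, heat shock and unfolded protein response, glycolysis and hypoxia, and sterol biosynthesis. Each list of at least 3 tested genes was compared with all other genes by camera, with a preset correlation of 0.01, the probe set of highest mean per gene, and adjustment over the lists of a comparison. The camera test was repeated with an estimated correlation. Also run was fry, in its directional and mixed forms, which tests a list against no change and not against other genes.

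Genes were named by a rule: per comparison, among probe sets with 1 symbol that were called and whose 3 arrays per group did not overlap, the 10 largest rises and the 10 largest falls, with the probe set of highest mean over the 12 arrays for each gene; then Myod1, Myf5, Myog and Myf6; and up to 4 members of each list with the largest change, called or not. A gene named in one comparison may be given in another. Other names are marked as chosen after their values were seen. Responses against hrGFP share their control arrays, so their correlation was set beside 100 simulated sets of unchanged groups that share 3 controls, with arrays taken as independent.

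The lot and day formed 3 array batches: replicates 3 and 4 of MyoD, Myf5 and hrGFP; replicate 5 of the same groups; and the 3 myogenin arrays. Whether replicate numbers pair samples was checked by correlating the deviations of arrays from their group means, with 0.1 as the threshold set in advance. The correlations were 0.495, 0.394 and 0.827 for MyoD and hrGFP, and 0.121, 0.332 and 0.106 for Myf5 and hrGFP. For MyoD and Myf5 they were -0.00706, 0.108 and 0.108. The numbers were therefore taken to pair samples of MyoD and Myf5 with hrGFP, not with each other. This check cannot tell pairing from 1 array that stands apart in each group, as MyoD 5 and hrGFP 5 did. For Myf5 5 the hrGFP array of highest correlation was hrGFP 3, so pairing stays unsettled. Fits with the replicate number as a block are given where they change a call or move a count by over 1.5 times.

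The alternatives tried were no pseudocount, 4 times the pseudocount, no filter, a stricter filter at the 60th percentile (signal 41.2, 5940 probe sets), no normalization, median centring, no variance trend, only the 6 arrays compared, a replicate block, an array batch block, the arrays of batch 1 alone, array weights, only probe sets without suffixes that mark shared probes, and leaving out each array in turn. For single genes and lists a part of these was run. With no pseudocount, signals under 1 were set to 1 before the log2 transformation, so large changes there may depend on this floor. Fits without MyoD 5 and hrGFP 5, which had high 3' to 5' ratios of the beta-actin and Gapdh controls, were chosen after seeing the data. The steps were tested on simulated data for MyoD against hrGFP over 8485 probe sets, 200 of them changed: 26% of those at a log2 change of 1 were called, 76% at 2, 98% at 3 and 84% at -2, with 6 false calls. A simulated comparison without change gave 0 calls by limma. For a list of 30 genes the camera p was 1.41e-26 when shifted and 0.856 when not.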

Results

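RNA levels were measured on 12 arrays of mouse fibroblasts that lack functional MyoD and Myf5 and had been infected with a retrovirus for MyoD, Myf5, myogenin or hrGFP alone, with 3 arrays per group. MyoD, Myf5 and myogenin are transcription factors that drive skeletal muscle formation. The purpose given by the labels was to find the genes that MyoD or Myf5 changes in cells without their own copies. The median deposited signal per array ran from 16.3 to 35.9, and the number of arrays limits the precision. Changes are differences of mean quantile-normalized log2(signal + 6.3), given ± the standard error from limma with n = 3 arrays against 3, and p-values are adjusted over 8485 probe sets. The pseudocount of 6.3 understates changes where a group's signal is low. With no pseudocount all 60 changes called for named genes were larger, 23 of them by over 1.5 times in fold, and each of these 23 had a group mean of 3.08 to 4.22, under the 4.41 that the filter signal makes on this scale. Group means carry ± the standard deviation (SD, n = 3).

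Myog, the endogenous or transduced myogenin transcript, had deposited signals of 165 to 443 with MyoD, 46.1 to 111 with Myf5, 89.2 to 122 with myogenin and 24.2 to 53.1 with hrGFP. Myod1 signals were 41.3 to 54.1 with MyoD and 84.4 to 100 with myogenin, and the Myf5 probe set gave 27.1 to 143 over all 12 arrays. Myf6, the other member of the family, stayed between 3.08 and 20.0. Against hrGFP, Myod1 differed by 0.01 with MyoD, -0.02 with Myf5 and 0.61 with myogenin, and the Myf5 probe set by -0.22, -0.17 and -0.09 in the same order. Myf6 differed by -0.43, -0.54 and -0.42, and none of these values passed. The viral transcript need not contain the part of a gene that its probes match, so these values do not check which factor a sample received.

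MyoD raised transcripts of the contractile apparatus against hrGFP, a comparison that asks what MyoD changes in these cells. Acta1, the actin of skeletal muscle, had a mean of 10.00 ± 0.88 with MyoD and 3.81 ± 1.01 with hrGFP, a rise of 6.20 ± 0.67 (adjusted p = 0.000848). Tnnc1, a troponin C of slow and cardiac muscle, rose by 5.46 ± 0.44 (adjusted p = 5.1e-05), and Tnnt3, the fast skeletal troponin T, by 4.82 ± 0.46 (adjusted p = 0.000233). Chrnb1, a subunit of the muscle acetylcholine receptor, rose by 3.81 ± 0.30 (adjusted p = 5.1e-05). Myog rose by 2.87 ± 0.47 (adjusted p = 0.0167), by 3.52 without MyoD 5 and hrGFP 5 (adjusted p = 0.000496) and by 3.53 within array batch 1. By the probe set of highest mean per gene, the other largest rises were in Myl1 (4.22 ± 0.51), Myl4 (4.01 ± 0.57), Tnni1 (3.63 ± 0.60), Tnnt2 (3.40 ± 0.48) and Myh3 (3.39 ± 0.44), all coding for myosin or troponin chains, with adjusted p between 0.00209 and 0.0181. Without MyoD 5 the rise of Tnni1 was 4.28. With no pseudocount the rises were 7.38 for Acta1, 6.56 for Tnnc1, 6.82 for Tnnt3, 5.33 for Chrnb1, 4.73 for Myh3 and 4.59 for Myl4, whose signals with hrGFP were low. The other Myl4 probe set did not pass (adjusted p = 0.515). The enzyme gene Mcpt8, a granule protease of basophils, rose by 2.16 ± 0.37 (adjusted p = 0.0212), and Itga7, the laminin receptor of muscle cells, by 1.98 ± 0.25 (adjusted p = 0.0029). The second Itga7 probe set differed by 1.32 ± 0.49 without passing. Tnnc2 (2.03 ± 0.32), Mylpf (2.29 ± 0.37) and Hspb2 (1.53 ± 0.24), genes also named in another comparison, rose with adjusted p between 0.0132 and 0.0152.

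In all, limma called 35 probe sets for MyoD against hrGFP, all of them higher, for 30 genes, against 301 at an unadjusted p under 0.05. Without change, a share of 0.05 of the 8485 probe sets would be expected at such a p. The number was under that share here, with Myf5 against hrGFP and with MyoD against Myf5. It was above that share in each comparison with myogenin. In each of the 35 the arrays of the groups did not overlap, which was so for 5.28% of all probe sets, where chance gives 10%. With the replicate number as a block 35 were called, 30 of them the same. Within array batch 1, with 2 arrays per group, 28 were called, 23 of them the same, and with the batch as a block 36; batch 2 held 1 array per group. The MyoD 5 and hrGFP 5 arrays had high 3' to 5' ratios of the beta-actin and Gapdh controls, and without them 46 were called, 43 higher and 3 lower, 28 of them shared. Within batch 1 Tnnc2, Erbb3, Chrna1, Hspb2, Mef2a, Ryr1 and Inhbb did not pass (adjusted p 0.0926 to 0.626), and without MyoD 5 and hrGFP 5 Tnnc2, Mef2a, Ryr1 and Inhbb did not (0.0722 to 0.179). Without normalization Mcpt8, Erbb3, Hspb2, Mef2a, Ryr1, Eno3, Id2 and Inhbb did not pass (0.0521 to 0.962). With no pseudocount it was Tnnc2, Erbb3, Mef2a, Ryr1 and Eno3 (0.0510 to 0.204), and with no filter Mef2a and Eno3 (0.0673 and 0.0510). Without MyoD 4 the count was 15, without hrGFP 3 it was 18 and without MyoD 3 it was 23. Of the 22 called genes named for this comparison, list members included, Acta1, Tnnc1, Tnnt3, Myl1, Chrnb1, Myh3, Chrna1 and Itga7 passed whichever array was left out. Without MyoD 4, 14 of the 22 no longer passed (adjusted p 0.0527 to 0.243), among them Myl4, Tnni1, Tnnt2, Myog and Mcpt8. Without hrGFP 3 it was 12 (0.0616 to 0.166) and without MyoD 3 it was 11 (0.0635 to 0.193), with Tnni1, Myog and Mcpt8 in both. Without hrGFP 4, Mcpt8 and 5 others, 6 in all, no longer passed (0.0653 to 0.243). The number was 6 without MyoD 5 (0.0519 to 0.117), 6 without Myf5 5 (0.0529 to 0.0911), 4 without hrGFP 5 (0.0599 to 0.101), 4 without Myf5 3 (0.0504 to 0.0808), 4 without Myf5 4 (0.0528 to 0.0758), 4 without myogenin 3 (0.0582 to 0.0845), 2 without myogenin 6 (0.0542 to 0.0598) and 1 without myogenin 2 (0.0721), all of them among Mef2a, Ryr1, Eno3, Id2, Inhbb, Erbb3 and Tnnc2.

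**Figure D1:**
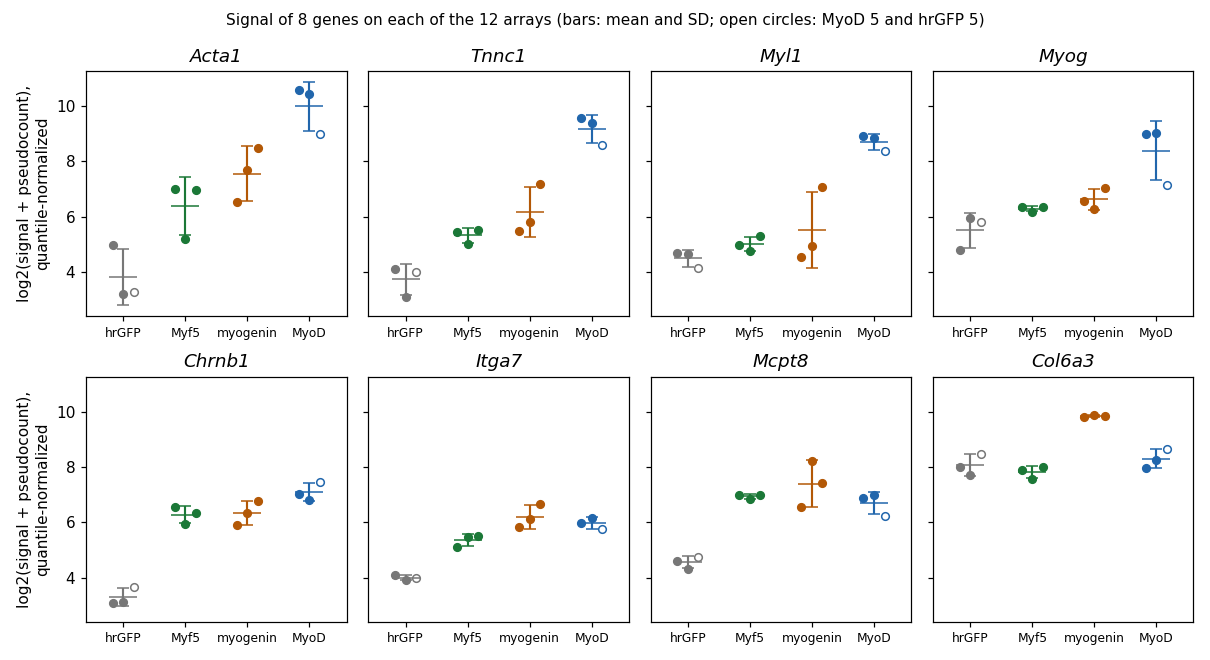
Quantile-normalized log2(signal + pseudocount) of 8 genes on each of the 12 arrays, by group, with the mean and SD of each group as bars; open circles mark the MyoD 5 and hrGFP 5 arrays. The Chrnb1 means were 7.10 with MyoD, 6.28 with Myf5, 6.34 with myogenin and 3.30 with hrGFP.

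The sarcomere and contraction list shifted up with MyoD, with a median change of 1.60 over 25 genes, of which 10 rose, 0 fell and 15 did not pass, 16 rising when adjusted over the list alone (camera adjusted p = 6.5e-39). In the neuromuscular junction list, median 0.91, Chrnb1 and the receptor subunit Chrna1 (2.45 ± 0.32, adjusted p = 0.00324) rose, 2 of 9, with 5 adjusted over the list alone (camera adjusted p = 4.69e-11). Muscle calcium handling had a median of 0.53, where the release channel Ryr1 (2.11 ± 0.37, adjusted p = 0.0283) was the 1 of 11 genes that rose, with 3 adjusted over the list alone (camera adjusted p = 1.59e-07). Muscle energy metabolism had a median of 0.35, and the enolase Eno3 (1.99 ± 0.37, adjusted p = 0.0436) was the 1 of 8 that rose, with 2 adjusted over the list alone (camera adjusted p = 0.00251; 0.153 without hrGFP 5). In myoblast adhesion and the dystrophin complex Itga7 was the 1 of 12 that rose, 2 when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00182). These 5 lists also passed with an estimated correlation, at adjusted p of 0.00607, 0.0257, 0.0257, 0.0314 and 0.0287 in that order by camera. For the sarcomere list the correlation was estimated at 0.207, against the preset 0.01, so its far smaller p rests on the preset. The estimates for muscle energy metabolism (-0.0330) and myoblast adhesion (-0.0197) were under the preset. The larger p of these lists thus did not come from a higher correlation of their own genes. Over all its alternatives the adjusted p of Chrna1 ran from 0.00176 to 0.101 and that of Ryr1 from 0.0113 to 0.174, and with no pseudocount their rises were 4.23 and 3.32.

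Among myogenic transcription factors, Myog and Mef2a (1.42 ± 0.27, adjusted p = 0.0468), a partner of the MyoD family, were the 2 of 13 that rose, with 3 adjusted over the list alone. The list had a median of 0.01 and a mean of 0.39, and its shift up (camera adjusted p = 0.0139) ended with an estimated correlation (adjusted p = 0.0571 with an estimated correlation). That estimate was 0.000105, under the preset 0.01, so a higher correlation between its genes did not end the shift. The shift also ended with the replicate block (0.0524) and without MyoD 3 (0.0767), hrGFP 3 (0.198) or hrGFP 5 (0.0993). Its median was negative without any of these 3 arrays or MyoD 4, and -0.04 with no filter. Cell cycle exit and D cyclins had a median of 0.30 with 0 of 19 genes passing, also adjusted over the list alone, by limma. Its camera adjusted p was 0.0139, and 0.197 with an estimated correlation. Against no change, the list had an adjusted p of 0.223 by directional and 0.368 by mixed fry. Its highest members were the retinoblastoma gene Rb1 (1.43 ± 0.43) and the cell cycle inhibitor Cdkn1a (1.09 ± 0.32), and the shift was lost without MyoD 5 (median -0.01, 0.245), hrGFP 3 (0.145) or hrGFP 4 (0.139). Mef2a had a blocked adjusted p of 0.0502 within a range of 0.0322 to 0.916 over its alternatives. The activin subunit Inhbb, 1.88 ± 0.33 (adjusted p = 0.0283), had a blocked value of 0.0785 within 0.0309 to 0.626 and a rise of 3.32 with no pseudocount. Erbb3, a neuregulin receptor, 2.16 ± 0.38 (adjusted p = 0.0286), had a blocked value of 0.0502 within 0.0127 to 0.204 and a rise of 2.80 with no pseudocount.

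Id2, a blocker of MyoD-type factors, rose by 1.59 ± 0.29 (adjusted p = 0.0392) as the 1 of 14 inhibitors of myogenesis that did, also when adjusted over the list alone (median 0.10, camera adjusted p = 0.369). Over its alternatives the adjusted p of Id2 ran from 0.0127 to 0.962, the latter without normalization, and it no longer passed in 10 of 19. Inhbb was the 1 of 14 genes of TGF-beta and BMP signalling that rose, also adjusted over the list alone; the median was -0.06 while the mean was 0.08 and the test pointed up (adjusted p = 0.883). In the insulin-like growth factor system 0 of 8 genes passed by limma, though 1 rose and 1 fell adjusted over the list alone (Igf2 1.02 ± 0.35, Igfbp2 -1.03 ± 0.30; median -0.06, adjusted p = 0.883). A probe set listed with both H19, a member of this list, and Mir675 was left out, since lists used probe sets with 1 symbol. It rose by 4.34 with MyoD and was called, and is named after its values were seen. No gene passed, in either adjustment, in the remaining lists with MyoD. Their medians and camera adjusted p were -0.01 and 0.898 for 32 genes of cell cycle and DNA replication, -0.14 and 0.369 for 36 of fibroblast and extracellular matrix, and -0.07 and 0.898 for 9 of interferon response. Smooth muscle markers (7 genes) had -0.23 and 0.896, cardiac markers (4) 0.04 and 0.883, adipocyte markers (5) -0.02 and 0.898, macrophage and leukocyte markers (5) -0.04 and 0.896, and neural markers (5) -0.02 and 0.896. Heat shock and unfolded protein response (15) had -0.02 and 0.898, glycolysis and hypoxia (14) 0.22 and 0.0711, and sterol biosynthesis (10) 0.16 and 0.686. For smooth muscle, adipocyte and heat shock genes the test pointed up although the median was negative, with means of -0.02, 0.07 and 0.01. Glycolysis and hypoxia passed without MyoD 5 and hrGFP 5 (adjusted p = 0.00286). Cartilage and bone, endothelial and epithelial markers had 2 tested genes each and were not tested, with medians of 0.43, -0.29 and -0.14.

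Several muscle genes were called with MyoD by a probe set other than the one of highest mean, and are named after their values were seen. Actc1, the cardiac actin, rose by 5.47 on one probe set (adjusted p = 0.000192) and did not pass on that of highest mean (adjusted p = 0.28). Tnnt1, the slow troponin T, rose by 3.39 (adjusted p = 5.1e-05) and differed by 0.58 on the other.

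Chrnb1 was the 1 probe set called for Myf5 against hrGFP, a comparison that asks what Myf5 changes in the same cells. It rose by 2.99 ± 0.30 (adjusted p = 0.00243), from 3.30 ± 0.33 to 6.28 ± 0.31, and passed whichever array was left out. With no pseudocount the rise was 4.46, since its signal with hrGFP was low. Mcpt8 came next in the test among the genes named, at 2.40 ± 0.37 (adjusted p = 0.0694), with means of 6.95 ± 0.10 and 4.55 ± 0.22. With the replicate number as a block Mcpt8 passed, at 2.43 (adjusted p = 0.0182), and without MyoD 5 and hrGFP 5 it did not (adjusted p = 0.0588). Acta1 differed by 2.58 ± 0.67, Tnnc1 by 1.60 ± 0.44, Tnnt3 by 1.38 ± 0.46 and Myog by 0.78 ± 0.47, each with an adjusted p of 0.973. Itga7 differed by 1.37 ± 0.25 (adjusted p = 0.243) and the platelet-derived growth factor receptor gene Pdgfra by -1.42 ± 0.30 (adjusted p = 0.564). By limma 254 probe sets had an unadjusted p under 0.05, and 8.66% did not overlap, where chance gives 10%. With the replicate number as a block 4 were called, as with the batch as a block and within batch 1, each time with Chrnb1, and with Mcpt8 under the replicate block. The count was 3 without MyoD 5, myogenin 2 or myogenin 3, and 2 without hrGFP 5.

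Of the 21 gene lists tested with Myf5, 0 shifted by camera, with a lowest adjusted p of 0.189, and 0 by directional fry, while mixed fry called 1, the neuromuscular junction. The sarcomere and contraction list had a median of 0.25 with 0 of 25 genes passing and 2 rising when adjusted over the list alone (adjusted p = 0.189). The neuromuscular junction list, where Chrnb1 rose, had a median of 0.25 (adjusted p = 0.189), and cell cycle and DNA replication one of 0.15 (adjusted p = 0.189). Adjusted over the list alone, 1 gene rose in myoblast adhesion, 1 rose among inhibitors of myogenesis and 1 fell in extracellular matrix. Without Myf5 4, 2 lists were called, and without hrGFP 3, 1 was.

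Chrnb1 also rose with myogenin against hrGFP, by 3.04 ± 0.30 (adjusted p = 0.00196), together with Mcpt8, by 2.85 ± 0.37 (adjusted p = 0.00643). Igf2, a growth factor made by differentiating muscle cells, rose by 2.71 ± 0.35 (adjusted p = 0.00643) from 4.86 ± 0.11 to 7.57 ± 0.57. Raly, coding for an RNA-binding protein, rose by 2.51 ± 0.27 (adjusted p = 0.00235), Itga7 by 2.20 ± 0.25 (adjusted p = 0.00379) and the collagen gene Col6a3 by 1.77 ± 0.24 (adjusted p = 0.00917). Gzmd, a granzyme gene, rose by 2.79 ± 0.47 (adjusted p = 0.0468), and Ank, a pyrophosphate transporter gene, fell by 1.69 ± 0.28 (adjusted p = 0.0398). The Gzmd probe set carries a suffix that marks shared probes, so its signal may not be of Gzmd alone. With no pseudocount the rises of Chrnb1, Gzmd and Itga7 were 4.52, 4.31 and 2.80, and without myogenin 2 that of Gzmd was 3.48. Acta1 differed by 3.76 ± 0.67 and Tnnc1 by 2.44 ± 0.44 (adjusted p = 0.0544 for both), and the protease gene Mmp3 by -2.03 ± 0.35 (adjusted p = 0.0516). Without MyoD 5 and hrGFP 5 these 3 passed (adjusted p = 0.0396, 0.0283 and 0.0442). The myogenin arrays formed an array batch of their own, so in each comparison with myogenin the batch and the group cannot be told apart.

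For myogenin against hrGFP limma called 11 probe sets, 10 higher and 1 lower, against 975 at an unadjusted p under 0.05, and 18.1% of probe sets did not overlap, where chance gives 10%. The count was 32 without MyoD 5, 7 without myogenin 6, and 48 without MyoD 5 and hrGFP 5 together (30 higher, 18 lower, all 11 shared). Chrnb1, Mcpt8, Igf2, Raly and Itga7 passed whichever array was left out. Col6a3 did not without hrGFP 4 or myogenin 2 (both 0.0510), myogenin 3 (0.0624) or myogenin 6 (0.0790). Ank did not without Myf5 3 (0.0715), Myf5 5 (0.0769), hrGFP 4 (0.131), hrGFP 5 (0.0956), myogenin 2 (0.131), myogenin 3 (0.118) or myogenin 6 (0.168). Gzmd passed without MyoD 5 or myogenin 2 and without no other single array, at an adjusted p of 0.0674 to 0.273. Without normalization Col6a3 (0.422) and Ank (0.387) did not pass, and with no filter Gzmd (0.0619) did not.

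With myogenin 6 lists shifted up, none with an estimated correlation. Neuromuscular junction had a median of 0.72 with Chrnb1 as the 1 of 9 that rose and 4 adjusted over the list alone (camera adjusted p = 9.75e-06; adjusted p = 0.153 with an estimated correlation). In sarcomere and contraction, median 0.75, 0 of 25 passed by limma and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.11e-07; adjusted p = 0.153 with an estimated correlation). In extracellular matrix, median 0.47, 0 of 36 passed, with 6 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00287; adjusted p = 0.153 with an estimated correlation). Its largest member was the matrix gene Postn, at 2.45 ± 0.49 (adjusted p = 0.0798; 5.24e-05 without MyoD 5 and hrGFP 5), and the shift ended without normalization (0.0987). In calcium handling, median 0.53, 0 of 11 passed and 1 rose adjusted over the list alone (camera adjusted p = 0.0055; adjusted p = 0.153 with an estimated correlation; 0.0681 without myogenin 6). Myogenic transcription factors had a median of 0.41 with 0 of 13 passing in either adjustment (camera adjusted p = 0.0431; adjusted p = 0.153 with an estimated correlation). That shift ended without MyoD 4 (0.0518), hrGFP 3 (0.329), hrGFP 4 (0.0822), myogenin 3 (0.0756) or myogenin 6 (0.107), with no filter (0.0603), without normalization (0.0978) and with the mean over probe sets (0.143). Smooth muscle markers had a median of 0.66 with 0 of 7 passing and 1 rising adjusted over the list alone (camera adjusted p = 0.0225; adjusted p = 0.364 with an estimated correlation). That shift ended without hrGFP 4 (0.112), hrGFP 5 (0.0721), myogenin 2 (0.0649) or myogenin 3 (0.0756), and without MyoD 5 and hrGFP 5 together (0.0530). It also ended with no filter (0.0603) and without normalization (0.216). Against no change, smooth muscle markers did not pass by directional (0.252) or mixed fry (0.287). In the insulin-like growth factor system Igf2 was the 1 of 8 that rose (median 0.24, camera adjusted p = 0.146). The probe set listed with H19 and Mir675, left out of this list, rose by 3.89 and was called.

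**Figure D2:**
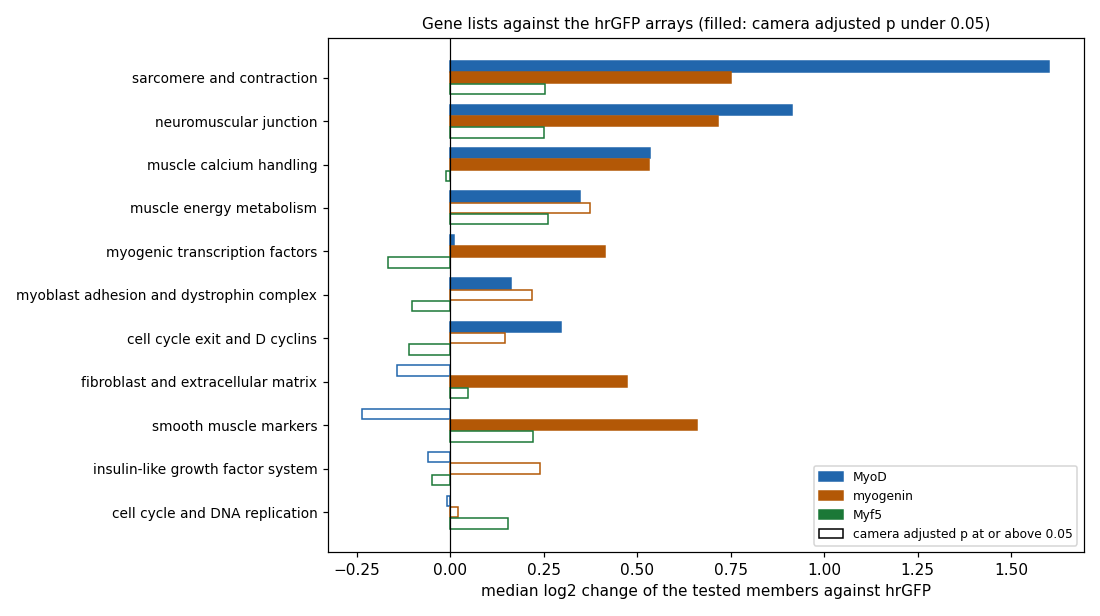
Median log2 change against hrGFP of 11 gene lists for MyoD, myogenin and Myf5; filled symbols mark a camera adjusted p under 0.05. The sarcomere and contraction medians were 1.60 with MyoD, 0.75 with myogenin and 0.25 with Myf5.

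The direct comparison of MyoD with Myf5 asks where the effects of the factors differ, and the genes called were higher with MyoD. Tnnc1 was higher by 3.86 ± 0.44 (adjusted p = 0.00285), with means of 9.19 ± 0.52 and 5.33 ± 0.28, and the myosin light chain gene Myl1 by 3.70 ± 0.51 (adjusted p = 0.011). Tnnt3 was higher by 3.44 ± 0.46 (adjusted p = 0.00867), the embryonic myosin gene Myh3 by 3.42 ± 0.44 (adjusted p = 0.00722) and Myl4 by 3.36 ± 0.57 (adjusted p = 0.0318). The other Myl4 probe set differed by 0.48 (adjusted p = 0.937). Tnnc2, the fast troponin C, was higher by 2.81 ± 0.32 (adjusted p = 0.00285). Erbb3 (2.49 ± 0.38), Mylpf (2.23 ± 0.37), Chrna1 (2.17 ± 0.32) and the small heat shock gene Hspb2 (1.69 ± 0.24) had adjusted p between 0.011 and 0.0263. Acta1 differed by 3.62 ± 0.67 (adjusted p = 0.0633), Myog by 2.10 ± 0.47 (adjusted p = 0.193), Chrnb1 by 0.82 ± 0.30 (adjusted p = 0.937), Itga7 by 0.61 ± 0.25 and Mcpt8 by -0.24 ± 0.37. Without MyoD 5 and hrGFP 5 the Myog difference was 2.63 (adjusted p = 0.00322) and that of Acta1 4.07 (adjusted p = 0.0166), and Chrna1 did not pass (adjusted p = 0.0598).

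For MyoD against Myf5 limma called 19 probe sets, all higher with MyoD, for 17 genes, against 314 at an unadjusted p under 0.05, and 9.76% of probe sets did not overlap, where chance gives 10%. Within batch 1, 20 were called, 10 of them shared, and 23 with the batch as a block. There Erbb3 (2.26, adjusted p = 0.185), Chrna1 (1.88, adjusted p = 0.340) and Hspb2 (1.79, adjusted p = 0.0603) did not pass within batch 1. With the replicate number as a block Mylpf (adjusted p = 0.0510) and Chrna1 (adjusted p = 0.0529) did not pass. Acta1 did (adjusted p = 0.0300), though the numbers were not taken to pair these samples. With no pseudocount Myh3 differed by 4.90, Erbb3 by 3.45 and Chrna1 by 3.51, and Myl4, Erbb3, Mylpf and Chrna1 did not pass (0.0694 to 0.146), and without normalization Mylpf (0.123) and Hspb2 (0.186) did not. Tnnc1 and Tnnc2 passed whichever array was left out. Of the 10 genes named above with an adjusted p under 0.05, 8 were lost without MyoD 3 (0.0523 to 0.151) or MyoD 4 (0.0839 to 0.223), 6 without Myf5 3 (0.0518 to 0.154) and 5 without Myf5 4 (0.0624 to 0.214). It was 4 without Myf5 5 (0.0663 to 0.0881), Erbb3 without MyoD 5 (0.0517), and Myl4 without hrGFP 3 (0.0577), hrGFP 4 (0.0516) or myogenin 3 (0.0559). The count was 4 without MyoD 3 or MyoD 4, 6 without Myf5 3, 8 without Myf5 5, 12 without Myf5 4 and 29 without MyoD 5. Without MyoD 5 and hrGFP 5 together it was also 29, with 28 higher, 1 lower and 14 shared.

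The sarcomere and contraction list was higher with MyoD than with Myf5, with a median of 1.54 and 7 of 25 genes called, 15 adjusted over the list alone (camera adjusted p = 2.87e-28). Calcium handling had a median of 0.63 with 0 of 11 genes called and 3 adjusted over the list alone (camera adjusted p = 2.43e-06). Myogenic transcription factors had a median of 0.14 with 0 of 13 called and 2 adjusted over the list alone (camera adjusted p = 0.00262). These 3 lists also passed with an estimated correlation. Over all their alternatives, that one included, their adjusted p was at most 0.0177, 0.0433 and 0.0495 in that order. Neuromuscular junction had a median of 0.66 with Chrna1 as the 1 of 9 called and 2 adjusted over the list alone (camera adjusted p = 5.08e-06; adjusted p = 0.0837 with an estimated correlation). Myoblast adhesion had a median of 0.26 with 0 of 12 called and 2 adjusted over the list alone (camera adjusted p = 0.00795; adjusted p = 0.0593 with an estimated correlation; 0.183 without MyoD 4). Cell cycle and DNA replication was lower with MyoD, with a median of -0.10 and 0 of 32 called in either adjustment by limma (camera adjusted p = 0.0364; adjusted p = 0.380 with an estimated correlation). That shift ended within batch 1 (0.111), without normalization (0.228) and without MyoD 4 (0.314), Myf5 3 (0.173) or Myf5 5 (0.169). Against no change, the list did not pass by directional (0.401) or mixed fry (0.765).

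Against myogenin, which the labels call a control, MyoD had 22 probe sets higher and 13 lower, with genes of the contractile apparatus among the first and collagen genes among the second. Tnnc1 was higher with MyoD by 3.02 ± 0.44 (adjusted p = 0.0174), Myl1 by 3.20 ± 0.51 and Myh3 by 2.76 ± 0.44 (adjusted p = 0.0236 for both). Raly was lower by -2.61 ± 0.27 (adjusted p = 0.00148), with means of 5.03 ± 0.19 and 7.64 ± 0.25. The collagen genes Col6a3 (-1.55 ± 0.24, adjusted p = 0.0236) and Col1a1 (-1.55 ± 0.26, adjusted p = 0.0274) and the perlecan gene Hspg2 (-1.66 ± 0.31, adjusted p = 0.048) were lower, as was the other Col1a1 probe set (-2.44, adjusted p = 0.0158). Also lower were the synaptic scaffold gene Dlg4 (-2.25 ± 0.36), the homeobox gene Hoxb9 (-1.88 ± 0.30) and the immunoglobulin gene Igh-VS107 (-1.37 ± 0.26). Higher were the histone gene H1f2 (2.17 ± 0.38), Tnnt3 (2.38 ± 0.46), Tnnc2 (1.81 ± 0.32), Chrna1 (1.73 ± 0.32), the collagenase gene Mmp13 (1.52 ± 0.27), the chromatin gene Pbrm1 (1.45 ± 0.22) and Ramp3 (1.42 ± 0.27), a receptor partner. These had adjusted p between 0.0236 and 0.0497, and the other Pbrm1 probe sets differed by 0.74, 0.40 and 0.03. Myog differed by 1.76 ± 0.47 (adjusted p = 0.161), and by 2.30 without MyoD 5 and hrGFP 5 (adjusted p = 0.00771). In that fit Tnnc2 (adjusted p = 0.0584), Chrna1 and Ramp3 (adjusted p = 0.0958 for both) did not pass. Without normalization Col6a3 (adjusted p = 0.480), Col1a1 (adjusted p = 0.397) and Hspg2 (adjusted p = 0.232) did not pass. With no pseudocount the differences were -3.52 for Dlg4, -3.18 for Hoxb9, 3.56 for Myh3, 2.95 for H1f2, 2.47 for Chrna1 and 2.22 for Ramp3, where 1 group had low signal. Without myogenin 6 they were 4.00 for Myl1 and 3.05 for Tnnt3.

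For MyoD against myogenin limma called 35 probe sets, 22 higher and 13 lower, against 1172 at an unadjusted p under 0.05, and 22.4% of probe sets did not overlap, where chance gives 10%. Of the 17 called genes named for it, 11 no longer passed without normalization (0.0633 to 0.480), 14 with no pseudocount (0.0524 to 0.199) and 7 with no filter (0.0538 to 0.0817). Raly passed in each of these and whichever array was left out. Without MyoD 4, 16 were lost (0.101 to 0.264), as without myogenin 2 (up to 0.293) and myogenin 3 (0.0681 to 0.184). It was 13 without MyoD 5 (0.0533 to 0.200), 12 without myogenin 6 (0.0899 to 0.191), 10 without Myf5 5 (0.0515 to 0.0993) and 9 without MyoD 3 (0.0510 to 0.0674). It was 8 without Myf5 3 (0.0552 and above) or Myf5 4 (0.0624 to 0.0851), 7 without hrGFP 3 (0.0550 to 0.0752) and 6 without hrGFP 4 (0.0538 to 0.0750). The count was 3 without myogenin 2, 5 without MyoD 4, 8 without myogenin 3, 9 without myogenin 6, 10 without MyoD 5, 14 without Myf5 5, 16 without Myf5 3, 19 without Myf5 4, 20 without hrGFP 3 and 58 without hrGFP 5. Without MyoD 5 and hrGFP 5 together it was 53, with 31 higher, 22 lower and 29 shared.

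The sarcomere and contraction list was higher with MyoD than with myogenin, with a median of 0.80 and 5 of 25 genes called, 7 adjusted over the list alone (camera adjusted p = 4.9e-07; adjusted p = 0.358 with an estimated correlation). Extracellular matrix was lower, with a median of -0.53 over 36 genes, of which Mmp13 was higher, Col1a1 lower and the others did not pass, with 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.000203; adjusted p = 0.214 with an estimated correlation, 0.0574 without normalization). Without MyoD 5, 4 lists were called.

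Col6a3 and Raly were the genes called for Myf5 against myogenin. Col6a3 was lower with Myf5 by -2.04 ± 0.24 (adjusted p = 0.0169), with means of 7.82 ± 0.22 and 9.86 ± 0.04, and Raly had means of 5.65 ± 0.48 and 7.64 ± 0.25 (adjusted p = 0.0174). Igf2 differed by -1.71 ± 0.35 and the matrix protease gene Mmp3 by 1.71 ± 0.35 (adjusted p = 0.218 for both), and Igf2 passed without MyoD 5 and hrGFP 5 (adjusted p = 0.0369). Limma called 3 probe sets, all lower, one of them listed with several genes, against 779 at an unadjusted p under 0.05, and 26.4% of probe sets did not overlap, where chance gives 10%. The count was 44 without MyoD 5 and hrGFP 5, which enter the spread but not the comparison, with 22 higher, 22 lower and 3 shared. With the 6 arrays compared alone it was 141. It was 5 without MyoD 3, 1 without myogenin 3, and 0 without Myf5 3, Myf5 4, myogenin 2 or myogenin 6. Both genes were lost without Myf5 3 (0.0916), Myf5 4 (0.0953), myogenin 2 (0.162 for Col6a3, 0.183 for Raly), myogenin 3 (0.0719) or myogenin 6 (0.147), and without normalization (0.771 for Col6a3, 0.452 for Raly).

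With Myf5 6 lists were lower than with myogenin, none with an estimated correlation, and 0 genes of any of them passed by limma. Against no change, none of these lists passed by directional fry (adjusted p 0.0624 to 0.145). Sarcomere and contraction had a median of -0.66, with 2 genes lower adjusted over the list alone (camera adjusted p = 7.53e-06; adjusted p = 0.255 with an estimated correlation). Its largest member was Myl4, at -1.81 ± 0.57. Neuromuscular junction had a median of -0.50, with 2 lower adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.257 with an estimated correlation). Calcium handling had -0.43, with 1 lower adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.177 with an estimated correlation), and its largest member was the calcium buffer gene Pvalb, at -1.39 ± 0.31 (adjusted p = 0.235; 0.0369 without MyoD 5 and hrGFP 5). Extracellular matrix had -0.37, with 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.177 with an estimated correlation). Myogenic transcription factors had -0.32, with 1 lower adjusted over the list alone (camera adjusted p = 0.00497; adjusted p = 0.177 with an estimated correlation). The insulin-like growth factor system had -0.24, with 2 lower adjusted over the list alone (camera adjusted p = 0.0358; adjusted p = 0.257 with an estimated correlation). That shift ended without Myf5 3 (0.165), myogenin 3 (0.0600) or myogenin 6 (0.0531), with no filter (0.0775) and with the mean over probe sets (0.0847). The shift of extracellular matrix ended without normalization (0.0756). Against no change, sarcomere and neuromuscular junction did not pass by mixed fry (0.109 for both).

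Chrnb1 was the 1 probe set that rose with all 3 factors against hrGFP. With MyoD and myogenin 5 probe sets rose in common, among them Itga7, Chrnb1, Mcpt8 and the one listed with H19 and Mir675. For Myf5 with MyoD or with myogenin it was Chrnb1 alone. Simulated unchanged groups that share their controls had a mean of 0 called in common for MyoD with either factor and 0.02 for Myf5 with myogenin. Groups without change give almost no calls, so a count near 0 was set in advance. It does not tell how many would be shared when each factor changes genes. Across genes, which are not independent replicates, the changes with MyoD correlated at 0.391 with those of Myf5 and 0.321 with those of myogenin, and those of Myf5 and myogenin at 0.603. These simulated groups gave 0.501, 0.501 and 0.501 in 100 simulations that took arrays as independent. Replicate numbers may pair MyoD and Myf5 with hrGFP. The covariance differed from the simulated one by -0.00934 for MyoD and Myf5, -0.00600 for MyoD and myogenin and 0.0566 for Myf5 and myogenin, and without MyoD 5 and hrGFP 5 by 0.0390, 0.0407 and 0.0154. In that fit the correlations were 0.592, 0.475 and 0.468 against simulated values of 0.546, 0.547 and 0.600, and 14 probe sets rose with both MyoD and myogenin. The simulated values already carry the shared controls, but not ties between arrays. With 3 controls, too few to give each factor several of its own, no excess is read as a shared response. Without MyoD 3 the correlations of MyoD with Myf5 and myogenin were 0.122 and 0.0379, without MyoD 4 they were 0.172 and 0.169, and without MyoD 5 they were 0.660 and 0.576. They were 0.629 and 0.533 without hrGFP 3, and the second was 0.557 without hrGFP 4. The number that rose with MyoD and myogenin was 10 without MyoD 5 and 2 without hrGFP 4. For Myf5 with either factor it was 3 without MyoD 5 or myogenin 2, 2 without hrGFP 5, and without myogenin 3 it was 3 with MyoD and 2 with myogenin.

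Control probe sets for beta-actin showed ratios of 3' to 5' signal of 25.7 on the MyoD 5 array and 37.6 on the hrGFP 5 array, and of 0.968 to 1.11 on the others. For Gapdh the ratios were 32.4 and 33.0, against 0.786 to 1.03. For the transferrin receptor they were 7.03 and 1.82, against 1.90 to 4.28, and for pyruvate carboxylase 4.50 and 2.61, against 1.55 to 4.90. The 5' signals of these other controls were at most 50.8 on any array, and on MyoD 5 and hrGFP 5 they were 2.75 and 11.8 for the transferrin receptor and 14.5 and 24.1 for pyruvate carboxylase.

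**Figure D3:**
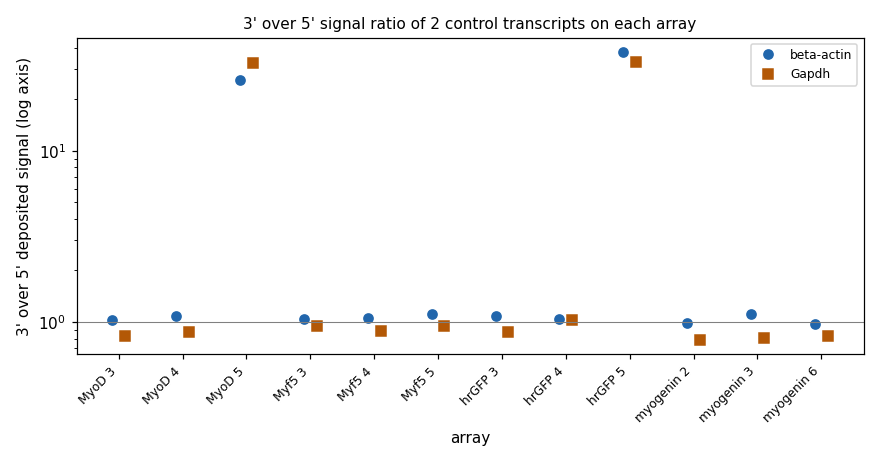
Ratio of deposited 3' to 5' signal of the beta-actin and Gapdh control probe sets on each of the 12 arrays, on a log axis. The MyoD 5 and hrGFP 5 arrays lie at 25.7 to 37.6 and the other 10 between 0.786 and 1.11.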

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

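Of the tests in this part, the one on spike-in controls was written before its values were seen, and those on 3' to 5' ratios and on the array lot were chosen only after the result was seen.

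The MyoD 5 and hrGFP 5 arrays stood apart in data outside the expression comparisons: their beta-actin ratios of 3' to 5' signal were 25.7 and 37.6 and their Gapdh ratios 32.4 and 33.0, 4 of 4 above the highest of the other 10 arrays, as was 1 of 4 for the weaker transferrin receptor and pyruvate carboxylase controls. Their expression values correlated at 0.958 with each other and at most at 0.836 with another array, while the other 10 correlated at 0.902 or more. The control for the middle of 18S ribosomal RNA had a signal of 2.44 on MyoD 5 and 3.28 on hrGFP 5, against 32.7 to 1682 on the other 10. No test was set on this control. For a fault in hybridization or scanning, 1 of 4 spike-in controls had ratios outside the range of the other arrays on both, fewer than the test asked for. This was Cre (1.74 and 1.60 against 1.37 to 1.58). On MyoD 5 alone BioC (0.959 against at most 0.877) and BioDn (6.55 against at most 6.07) lay above it too, and BioDn was 6.04 on hrGFP 5. A ratio within 1 control cancels a change common to the whole array, so such a fault stays open. The Myf5 5 array of the same lot and day had a mean correlation of 0.942 with the 9 arrays of other batches, above the lowest of those, 0.920. Lot and day thus did not set every array of the batch apart. With 1 such array, an effect on part of the batch stays open. RNA or labelled target shortened toward the 3' end may explain the pattern, though on hrGFP 5 the transferrin receptor ratio, 1.82, lay below the others and the pyruvate carboxylase ratio, 2.61, within them, at 5' signals of 11.8 and 24.1; no biological explanation was tested, and the groups hold 3 arrays, too few for a test of single arrays.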

How the results depend on the processing

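The fits without MyoD 5 and hrGFP 5 were chosen after seeing the data; the other alternatives were planned. Genes and lists were recomputed under no pseudocount, no filter, no normalization, the blocks, batch 1 alone, the fits without those 2 arrays and leaving out 1 array, and there no called gene changed sign and no camera shift its direction. For MyoD against hrGFP the median of myogenic transcription factors fell as low as -0.04 and that of cell cycle exit as low as -0.01. The median of sarcomere and contraction ran from 0.80 to 1.93 there.

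Of the 60 gene results that passed, 23 no longer did with no pseudocount, 25 without normalization, 10 with no filter and 8 without MyoD 5 and hrGFP 5; 261 of 720 calls were lost on leaving out 1 array. Of the 27 list results, 19 no longer passed with an estimated correlation, 6 without normalization and 24 of 324 on leaving out 1 array. A loss with the estimated correlation need not mean correlated genes. For myogenic transcription factors the estimate was 0.000105, under the preset 0.01. Tested against no change, 9 of the 27 did not pass by directional fry and 5 by mixed fry. With the replicate block 5 of 33 genes and 1 of 13 lists were lost, with the batch block 1 and 0, and within array batch 1 10 and 1. No batch block could be had for comparisons with myogenin, and batch 2 held 1 array per group. In fits that leave out an array the group of 2 is assumed to vary like the others.

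Called probe sets, in the order MyoD, Myf5 and myogenin against hrGFP, MyoD against Myf5, and MyoD and Myf5 against myogenin, were 35, 1, 11, 19, 35 and 3. Leaving out 1 array gave 15 to 36, 1 to 3, 7 to 32, 4 to 29, 3 to 58 and 0 to 5. With no pseudocount all but the first and last became 3, 17, 9 and 7, and 4 times the pseudocount gave 2 for Myf5 against hrGFP. No filter gave 2 for Myf5 against hrGFP and 23 for MyoD against myogenin, and the stricter filter 20 for myogenin against hrGFP. No normalization gave 22 for MyoD against hrGFP, 13 for MyoD against myogenin (7 higher, 6 lower) and 0 for Myf5 against myogenin; it shifted the median of all probe sets by 0.17 for myogenin against hrGFP and -0.17 for MyoD against myogenin. Median centring gave 15 (11 higher, 4 lower) and 0 for the comparisons of MyoD and Myf5 with myogenin. Myogenin against hrGFP had 16 higher and 0 lower without normalization and 8 and 0 with centring. Replicate block, batch block and batch 1 alone each gave 4 for Myf5 against hrGFP. For MyoD against Myf5, where numbers were not taken to pair samples, the replicate block called 18. Array weights gave 11, 457, 44, 164 and 1404 for all but the first. Probe sets without suffixes gave 2, 7, 12 and 13 for all but the first and last, where fewer were tested. Without MyoD 5 and hrGFP 5 all but the first were 2, 48, 29, 53 and 44. The 6 arrays compared alone, fewer for estimating the spread, gave 17, 3, 0, 11, 3 and 141. At the 0, 836 had an unadjusted p under 0.05 by limma. At the 141, MyoD 5 and hrGFP 5 are not among the arrays compared. The 3 called there in the fit to all arrays thus depends on the spread of arrays not compared.

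Lists called were 7, 0, 6, 6, 2 and 6 in that order, and leaving out 1 array gave 5 to 8, 0 to 2, 4 to 6, 5 to 7, 2 to 4 and 5 to 8. The estimated correlation gave 0, 3, 0 and 0 for the last 4. Mixed fry gave 1 for Myf5 against hrGFP and 7 for MyoD against myogenin, and directional fry 0 for Myf5 against myogenin. No normalization gave 3 for myogenin against hrGFP and 1 for MyoD against myogenin.

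Correlations of responses for MyoD and Myf5 were 0.42 with no pseudocount, 0.41 with no filter, 0.36 without normalization and 0.59 without MyoD 5 and hrGFP 5, and for MyoD and myogenin 0.36, 0.35, 0.30 and 0.48. For Myf5 and myogenin they were 0.62 with no pseudocount and 0.47 without the 2 arrays. Leaving out 1 array gave 0.12 to 0.66, 0.038 to 0.58 and 0.47 to 0.76. Probe sets that rose in common with MyoD and Myf5 were 3 with no pseudocount, 4 with the replicate block and 2 without the 2 arrays; with MyoD and myogenin 14 without the 2 arrays; and with Myf5 and myogenin 3 with no pseudocount and 2 without the 2 arrays. Leaving out 1 array gave 1 to 3, 2 to 10 and 1 to 3. The cause was not tested for any of these, except where fewer samples or probe sets were used. Signals near the 25th percentile, 6.3, limit what can be seen of weakly expressed genes.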

Other observations

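The 6 tests of other splits of the arrays were written before their values were seen; the other tests in this part were chosen only after the result was seen.

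Some muscle genes changed less with Myf5 than with MyoD: 19 probe sets were called between them, Tnnc1 and Myl1 among these, while Chrnb1 and Itga7 did not pass. A smaller share of responding cells in the Myf5 samples would give each gene the same share of its MyoD change on the linear scale. Over the 35 probe sets called for MyoD the median share was 0.0562. By limma 4 lay above it, Mcpt8 (1.24), Itga7 (0.539), Chrnb1 (0.533) and one not listed with a gene (0.653), at adjusted p of 0.000978 to 0.00986. The 35 were picked by their change against hrGFP arrays that also enter every share. Low hrGFP values by chance would thus favour shares above the median, which was itself taken as known without error. These p-values therefore do not settle whether such a share is the whole cause. The MyoD 5 and hrGFP 5 arrays were argued against as the cause, since without them 29 probe sets were called. A different level of the transduced factor, or a difference between the factors themselves, may explain the pattern and was not tested.

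Mcpt8 signal was higher with each of the 3 factors, by 2.16 ± 0.37 with MyoD, 2.40 ± 0.37 with Myf5 (adjusted p = 0.0694; 0.0182 with the replicate block) and 2.85 ± 0.37 with myogenin. For macrophages among the sorted cells, 5 of 11 listed markers were tested. Their highest median change was 0.17 (with myogenin, SD between markers 0.58) and the highest single change 0.50. This argues against macrophages as far as 5 markers can. With hrGFP, Fcgr3 (4.08) and Itgb2 (4.30) lay under the filter signal, 4.41 on this scale, and Cd68 (4.81) near it. For mast cells a list of 11 markers, none in another list, was written after some values had been seen. The 3 tested, Cma1, Mcpt1 and Tpsb2 (4.75, 4.68 and 6.04 with hrGFP), had a median change of at most -0.19 with any factor. No single change was above 0.26, which argues against mast cells as far as 3 markers can. Cma1 and Mcpt1 lay near the filter signal, 4.41 on this scale. The mean of the 3 factors against hrGFP called 10 probe sets, all higher and of the same sign with each factor, Mcpt8 among them at 2.47 ± 0.30 (adjusted p = 0.0033), but the comparisons share their hrGFP arrays, so this does not test for a shared response. A response shared by the factors and leukocytes other than those, such as basophils, where Mcpt8 is abundant, both stay open, though the cells had been sorted for fluorescence.

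Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. For MyoD against hrGFP 2 splits called at least the real 35, and the highest other called 857. That one set MyoD 5, hrGFP 5 and MyoD 4 against the rest. It keeps the pair of arrays with high control ratios on one side. Other splits that do so called fewer than the real one, and the cause was not tested. Among the 4 splits that part every replicate pair the highest other called 0, and without MyoD 5 and hrGFP 5 the real comparison called 46. In the other comparisons 1 split, the real one, called as many: 1 for Myf5 against hrGFP (highest other 0, and 0 among splits parting pairs), 11 for myogenin against hrGFP (1), 19 for MyoD against Myf5 (0), 35 for MyoD against myogenin (1) and 3 for Myf5 against myogenin (0).

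Granzyme genes of the cluster that holds Mcpt8 had values of their own. Gzmd differed from hrGFP by 1.62 ± 0.47 with MyoD (adjusted p = 0.51), 1.71 ± 0.47 with Myf5 (adjusted p = 0.973) and 2.79 ± 0.47 with myogenin. Its probe set carries a suffix that marks shared probes, so the signal may not be of Gzmd alone. Gzmg differed by -0.28, 0.07 and -0.18 and Gzmb by 0.81, -0.16 and 0.39 in the same order. Gzmg and Gzmb are named after their values were seen, and other genes of the cluster are not given.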
